A study of Homo sapiens with 6 samples.

How the data were processed

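The series holds 6 arrays of total RNA from FOCUS liver cancer cells, 3 with a control shRNA against GFP and 3 with an shRNA against PEA15, grouped by the sample titles. The authors deposited a table of log2 expression values, with 1 column per array and 47221 Illumina probes. Per the labels, RNA was isolated with a mirVana kit, its integrity was checked by electrophoresis and the arrays were labelled with Cy3. The software, background correction and probe filter behind the deposited log2 values are not given in the sources used here. The log2 scale was read from the values, which run from 6.41 to 14.4 with no missing value. Sorted values of the 6 columns differed by at most 0.001, so the table had been quantile normalized between arrays before it was deposited. The median was 6.85 on every array, the upper quartile 7.47 and the 95th percentile 10.6. No detection p-values were used here, so the level of background is unknown, values near the median cannot be told from background, and fold changes of dim genes may be compressed. Quantile normalization also removes any change in total RNA level shared by most genes.

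Probes were named through the platform's annotation. Of the probes, 30110 had 1 gene symbol, 8 had several and 17103 were unnamed in that table. Entrez identifiers were found for 30071 probes in a RefSeq gene table, and 0 symbols needed an update. Probes with several symbols or none were left out of the gene test. Of these 17111 probes, 333 passed when all probes were tested. Each of the 20044 genes was represented by its probe with the highest mean over all 6 arrays, with no filter on dim probes. No gene had probes called in both directions, and of 624 called genes with several probes above the table's median, 538 had all of these probes changing with the same sign.

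The values were used as deposited, with no further normalization. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust variance, no covariate), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. SEs of log2 changes are limma's moderated values, and SDs are over the 3 arrays of a group. The median residual SD was 0.084 and the prior had 4.92 degrees of freedom. PEA15 was also tested with a two-sided exact permutation test. Fixed before the data were examined were 33 gene lists with 649 members, of which 608 were measured; the others were not analysed here. Some genes stand in several lists. Each list was tested against all other genes with limma's camera, with its preset correlation of 0.01 between genes, and again with the correlation estimated from the arrays, adjusted over the lists. Fry tested whether the genes of a list move on balance in 1 direction, without comparing them with other genes. Counts adjusted over the list alone come from the same limma p-values. List means per array are relative to the mean of the shGFP arrays.

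Genes were named by a rule, also fixed beforehand: PEA15, then the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose mean lies above the median of all probes, leaving out unnamed predicted loci, then up to 4 members per list with the smallest p. USP18 and XAF1 were named after their values were seen, as were the gene families among the closing observations.

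The tests were tried on simulated data with the same 20044 genes and 3 arrays per group, in 10 simulations with 200 changed genes. The changed genes were drawn only from those with means above the table's median, so recovery among dimmer genes was not measured. Changes of 1.5-fold were recovered in 96.7% and of 2-fold in 99.7%, but the smallest changes simulated, below 1.5-fold, in only 40.9%, with 6.4% false among the calls. A list shifted by 0.3 on the log2 scale was called in 10 of 10 simulations, and 1 of 320 unchanged lists was called. Simulated noise was independent between genes, so these list counts do not show how often lists of correlated genes are called falsely. No arrays held the same data, since any 2 arrays shared at most 0.377% identical values. No batch, slide or date was given in the labels. Alternatives fixed beforehand were a replicate block, repeated quantile normalization, median centring, an offset of 50 before the log, other rules for the probe of a gene, all probes singly, brighter probes only (means above the table's median), other eBayes settings, array weights, each array left out, stricter thresholds (adjusted p under 0.01, a 1.5-fold change, and treat with a 1.2-fold limit), and camera on ranks. Counts of list members with each array left out were added after the data were examined. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.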

Results

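Gene expression was measured on Illumina bead arrays in FOCUS cells, a line derived from human hepatocellular carcinoma. The cells carried a short hairpin RNA (shRNA) against PEA15 or a control shRNA against GFP, a jellyfish protein with no human counterpart. PEA15 encodes a small death effector domain protein that binds the kinases ERK1 and ERK2 in the cytoplasm and also binds FADD, an adaptor of death receptors. There were 3 arrays with the control shRNA (shGFP) and 3 with the PEA15 shRNA (shPEA15). Each array gave a log2 value for 47221 probes, of which 30110 carried a single gene symbol, for 20044 genes. The labels do not say whether the replicates were separate cultures. The p-values therefore measure only the spread between these arrays, which may be technical, and their number limits the precision. The question the series asks is which transcripts differ when PEA15 is depleted.

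PEA15 itself was the most changed gene on the arrays. Its log2 value was 12.70 ± 0.073 (SD, n = 3) with shGFP and 9.69 ± 0.057 (SD, n = 3) with shPEA15. The difference of -3.00 ± 0.064 (SE) corresponds to an 8.02-fold lower signal, or 12.5% of control. PEA15 was read by 1 probe, ILMN_1771376. The shPEA15 arrays gave 9.63, 9.71 and 9.74, and the shGFP arrays gave 12.66, 12.78 and 12.65. The limma adjusted p was 1.04e-07. A two-sided exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow. The level of background in the values is unknown, and any that remains would make such fold changes smaller than the change in RNA.

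Beyond PEA15, the genes with the largest rises included GLO1, SPRY2, PMAIP1 and SRC, and those with the largest falls included FADS1, AKR1C3, PPARG and IGFBP3. GLO1, which encodes the glyoxalase that detoxifies methylglyoxal, rose 4.32-fold, from 8.88 ± 0.13 to 10.99 ± 0.28 (SD, n = 3 each). SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, rose 2.72-fold, from 9.06 ± 0.059 to 10.51 ± 0.081 (SD, n = 3 each). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose by 1.29 ± 0.13 on the log2 scale (SE, 3 arrays per group, as for every log2 change below). FADS1, a desaturase that makes polyunsaturated fatty acids, was 3.74-fold lower, at 10.20 ± 0.13 with shGFP and 8.29 ± 0.055 with shPEA15 (SD, n = 3 each).

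**Figure D1:**
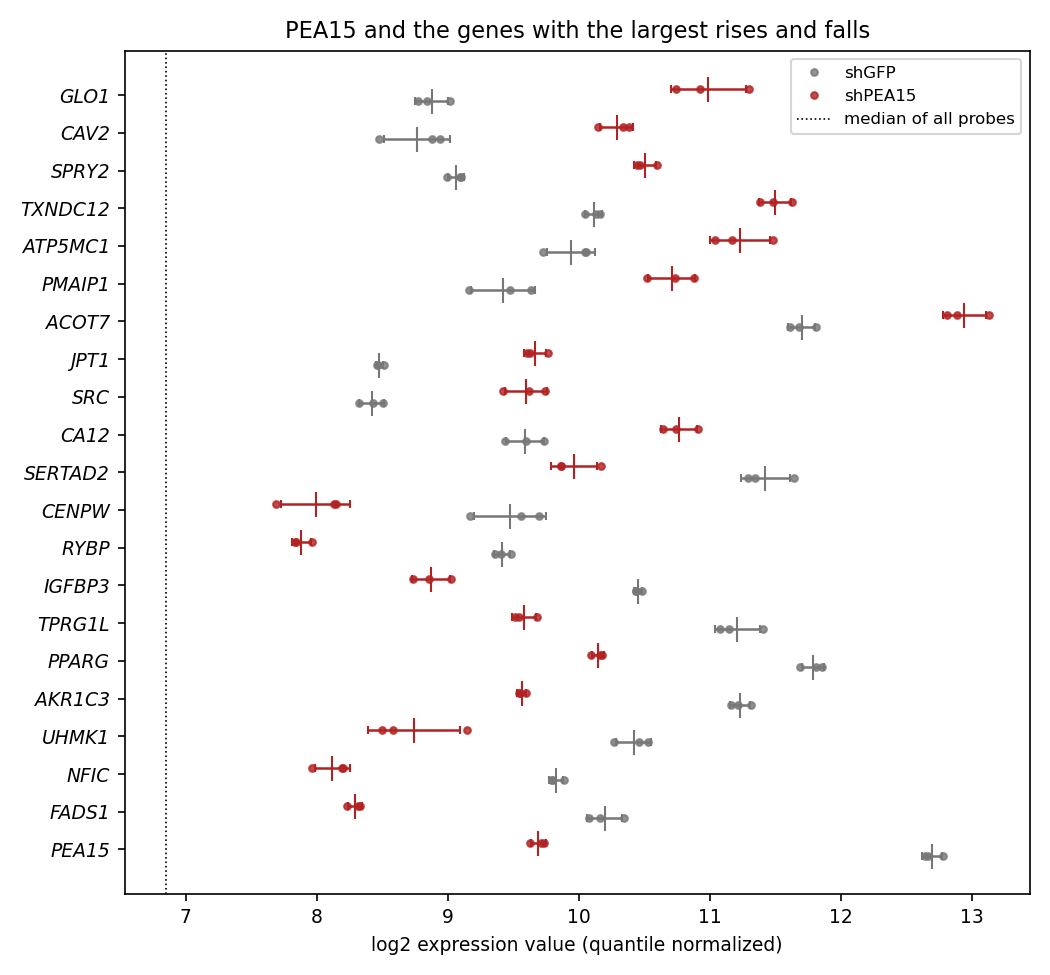
Log2 expression values (horizontal axis) of PEA15 and of the 10 genes with the largest rises and the 10 with the largest falls (vertical axis). Points are single arrays, grey for shGFP and red for shPEA15, vertical ticks are means of 3 arrays, bars are SDs, and the dotted line is the median of all probes. PEA15 lies near 12.7 in the shGFP arrays and near 9.69 in the shPEA15 arrays, and the arrays of the groups do not overlap for any gene shown.

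The other large rises were in genes of varied function. CAV2, a caveola protein, rose by 1.52 ± 0.12, TXNDC12, a thioredoxin-like protein of the endoplasmic reticulum, by 1.39 ± 0.075, and ATP5MC1, a subunit of ATP synthase, by 1.29 ± 0.13. ACOT7, an acyl-CoA thioesterase, rose by 1.24 ± 0.092, JPT1 by 1.19 ± 0.063, the tyrosine kinase gene SRC by 1.18 ± 0.090 and CA12, a carbonic anhydrase, by 1.17 ± 0.093. Among the falls, the transcription factor gene NFIC changed by -1.71 ± 0.077, the kinase gene UHMK1 by -1.68 ± 0.15 and AKR1C3, an aldo-keto reductase, by -1.66 ± 0.062. PPARG, the nuclear receptor of fat cell differentiation, changed by -1.64 ± 0.064, TPRG1L by -1.63 ± 0.092 and IGFBP3, a binding protein of insulin-like growth factors, by -1.58 ± 0.078. RYBP, a component of Polycomb complexes, changed by -1.53 ± 0.064, the centromere protein gene CENPW by -1.48 ± 0.16 and SERTAD2 by -1.46 ± 0.11. Adjusted p-values of these 20 genes in limma, with Benjamini-Hochberg adjustment, lay between 7.24e-06 and 0.000557. Where a gene had several probes, the brightest was used, and averaging all probes gave smaller changes for SRC (0.37), NFIC (-0.38), ACOT7 (0.50) and PPARG (-0.85), all still called. Of 3 probes for SRC, 1 was called, and of 5 for NFIC, 1 was called and 4 lay below the median of the table.

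Across the 20044 genes, 1870 changed (9.33%), 920 upward and 950 downward, at a limma adjusted p under 0.05. At least 2-fold changes were fewer, with 18 rises and 60 falls, while 1423 of the called genes changed by less than 1.5-fold. The median change of all genes was 0.005. Array values of the groups did not overlap for 4788 genes (23.9%), where chance gives 10%. The count of called genes fell from 1870 to 922 without shGFP replicate 1, to 1242 without shGFP replicate 2 and to 1189 without shGFP replicate 3. When the probes of a gene were averaged, 47 genes instead of 78 changed at least 2-fold. The array of shPEA15 replicate 3 stood apart. Across genes with means above the table's median, it correlated at 0.988 and 0.989 with the other shPEA15 arrays, against 0.996 between those arrays. Genes are not independent replicates. Without shPEA15 replicate 3, 2221 genes were called.

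Mitotic genes were lower in the cells with shPEA15. Of 26 measured members of the G2/M and mitosis list, 19 fell and 0 rose, and 25 fell and 0 rose when adjusted over the list alone. CENPF, a kinetochore protein, was 2.01-fold lower, at 9.81 ± 0.057 with shGFP and 8.81 ± 0.052 with shPEA15 (SD, n = 3 each, limma adjusted p = 4.06e-05), and CCNB2, a mitotic cyclin, by -0.57 ± 0.059 (adjusted p = 0.000548). KIF23, a kinesin of the midbody, changed by -0.92 ± 0.096, or by -0.52 with its 2 probes averaged, and the spindle protein gene NUSAP1 by -0.54 ± 0.077. The list mean changed by -0.48, with the shPEA15 arrays at -0.41, -0.49 and -0.54 and the shGFP arrays between -0.031 and 0.041. In limma's camera test the list was lower than other genes (adjusted p = 2.07e-19, and adjusted p = 0.0796 with an estimated correlation). The number that fell was 11 without shGFP replicate 1 or shGFP replicate 2, and 23 without shPEA15 replicate 3.

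Genes of G1/S and DNA replication were also lower, by less. Of 25 measured members, 7 fell and 0 rose, and 7 fell and 1 rose when adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, changed by -0.51 ± 0.064 (adjusted p = 0.00158), and CDT1, a replication licensing factor, by -0.48 ± 0.082 (adjusted p = 0.00679). The mean of the list changed by -0.15, and camera called it lower (adjusted p = 0.000984, and adjusted p = 0.165 with an estimated correlation). Of these genes, 2 fell without shGFP replicate 1, and 4 without shGFP replicate 2, shGFP replicate 3 or shPEA15 replicate 2. Leaving out shPEA15 replicate 3 gave 8 falls and 1 rise. Among 14 CDK inhibitors and quiescence genes, 2 rose and 1 fell, the same when adjusted over the list alone. KLF2, a transcription factor of quiescent cells, rose 2.15-fold, from 9.77 ± 0.079 to 10.87 ± 0.20 (SD, n = 3 each). CDKN1A, which encodes the CDK inhibitor p21, rose by 0.71 ± 0.099 (0.44 with its probes averaged), whereas CDKN1B, which encodes p27, changed by -0.44 ± 0.077 (-0.28 with its probes averaged). That list was not called (adjusted p = 0.645), its median lying just below 0 (-0.0005) with a mean of 0.11.

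Several targets and feedback inhibitors of ERK signalling were higher with shPEA15. Of the 24 measured members of the ERK pathway output list, 9 rose and 1 fell, the same when adjusted over the list alone. Besides SPRY2, the transcription factor gene KLF6 rose by 0.91 ± 0.079 (adjusted p = 0.000253) and DUSP5, a phosphatase that acts on ERK, by 0.85 ± 0.082 (adjusted p = 0.000383). CCND1, which encodes cyclin D1 and is commonly induced by ERK, moved the other way, by -1.23 ± 0.095 (adjusted p = 0.00014). The median of the list was 0.057 and its mean 0.21, and camera called it higher (adjusted p = 0.000924, and adjusted p = 0.276 with an estimated correlation). Of 16 measured PEA15 partners and ERK module genes, 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone. The kinase gene MAP2K1, encoding MEK1, rose by 0.88 ± 0.073 (adjusted p = 0.000194), DUSP6 by 0.55 ± 0.078 (0.33 with its probes averaged) and CAMK2G by 0.53 ± 0.076, and PRKCA, a protein kinase C gene, changed by -0.77 ± 0.073. Camera called this list higher (adjusted p = 0.0337, and adjusted p = 0.418 with an estimated correlation). The call was lost without shPEA15 replicate 3 (adjusted p = 0.198), shGFP replicate 2 (0.0616) or shGFP replicate 3 (0.0546), with probes averaged (0.0507), among brighter probes (0.128), on ranks (0.104) and with fry (0.0923).

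Interferon-stimulated genes were higher in the shPEA15 arrays. Of 23 measured members, 8 rose and 2 fell, and 12 rose and 2 fell when adjusted over the list alone. MX1, an antiviral GTPase, rose by 0.87 ± 0.11 (adjusted p = 0.00153), the ubiquitin-like modifier gene ISG15 by 0.68 ± 0.072 (adjusted p = 0.000589), and IRF9, a subunit of the factor that drives these genes, by 0.66 ± 0.055 (adjusted p = 0.000195). IRF7 rose by 0.60 ± 0.067, or by 0.29 with its probes averaged. The members that fell were USP18 (-0.25 ± 0.058) and XAF1 (-0.33 ± 0.078), both lost as calls without shGFP replicate 1 (adjusted p = 0.0944 and 0.112) and without some other arrays. Rises numbered 6 without shGFP replicate 1, 7 without shGFP replicate 3, 9 without shPEA15 replicate 1 and 12 without shPEA15 replicate 3. The list mean was 0.25 to 0.31 above control in the shPEA15 arrays, and camera called it higher (adjusted p = 9.43e-06, and adjusted p = 0.105 with an estimated correlation). Of 19 NF-kappaB and inflammatory genes, 1 rose and 3 fell, and 4 rose and 4 fell when adjusted over the list alone. The cytokine genes CXCL8 (-1.09 ± 0.14), IL1A (-0.85 ± 0.12) and IL1B (-0.40 ± 0.067) fell. RELB rose by 0.32 ± 0.080, a call lost without any array except shPEA15 replicate 1 (adjusted p up to 0.162), while 2 members rose without shGFP replicate 2. The list was not called (adjusted p = 0.807), with a median of 0.027 and a mean of -0.093.

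TGF-beta target genes were lower. Of 15 measured members, 5 fell and 1 rose, and 7 fell and 1 rose when adjusted over the list alone. PMEPA1, a feedback inhibitor of TGF-beta signalling, changed by -1.02 ± 0.097 (adjusted p = 0.000357), or by -0.47 with its probes averaged, and THBS1, a matrix protein, by -0.78 ± 0.14 (adjusted p = 0.00732). The inhibitory SMAD6 changed by -0.37 ± 0.074, a call lost without shGFP replicate 1 (adjusted p = 0.0793) or shGFP replicate 2 (0.0561). BHLHE40, a transcriptional repressor, rose by 0.45 ± 0.070. Camera called the list lower (adjusted p = 0.00106, and adjusted p = 0.165 with an estimated correlation). The number that fell was 2 without shGFP replicate 1 or shGFP replicate 2, and 3 without shPEA15 replicate 1 or shPEA15 replicate 2. Of 23 measured YAP and TAZ targets, 3 rose and 6 fell, and 3 rose and 7 fell when adjusted over the list alone. IGFBP3 and PTPN14 (-0.93 ± 0.073, or -0.47 with its probes averaged) fell, and MYOF (0.69 ± 0.065) and FJX1 (0.74 ± 0.080) rose. Camera did not call this list (adjusted p = 0.0942), except without shPEA15 replicate 1 (adjusted p = 0.0476), and fry called it lower (0.00742). In this list 5 rose and 6 fell without shPEA15 replicate 3.

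Genes of matrix proteolysis were higher on balance. Of 17 measured matrix protease and invasion genes, 4 rose and 1 fell, and 7 rose and 1 fell when adjusted over the list alone. MMP9, a gelatinase, rose by 1.00 ± 0.062 (adjusted p = 4.43e-05) and ADAMTS1 by 0.34 ± 0.056 (adjusted p = 0.00611). TIMP3, an inhibitor of such proteases, changed by -0.70 ± 0.091 (adjusted p = 0.0017). The urokinase receptor gene PLAUR rose by 0.40 ± 0.082, a call lost without shGFP replicate 1 (adjusted p = 0.0858). Camera called the list higher (adjusted p = 0.00317, and adjusted p = 0.165 with an estimated correlation). The number that rose was 2 without shGFP replicate 1 and 7 without shPEA15 replicate 3. Of 19 integrin and focal adhesion genes, 5 rose and 1 fell, and 5 rose and 2 fell when adjusted over the list alone. PTK2, which encodes focal adhesion kinase, rose by 1.06 ± 0.11 (0.62 with its 2 probes averaged), and VCL, which encodes vinculin, changed by -0.94 ± 0.10 (-0.49 with its probes averaged). The list was not called (adjusted p = 0.406). The number that rose was 2 without any 1 of the shGFP arrays and 3 without shPEA15 replicate 1 or shPEA15 replicate 2, and 2 fell without shPEA15 replicate 3. Of 19 mesenchymal markers, 3 rose and 1 fell, among them the collagen genes COL6A1 (0.97 ± 0.096) and COL5A1 (0.73 ± 0.11), which rose, and SNAI2 (-0.69 ± 0.10), which fell. Of 18 epithelial junction markers, 2 rose and 0 fell. These were the keratin gene KRT18 (0.50 ± 0.11) and the claudin gene CLDN3 (0.51 ± 0.10), both lost without shGFP replicate 1 (adjusted p = 0.0819 and 0.0803) or shGFP replicate 3 (0.0785 and 0.0619). KRT18 was also lost without shPEA15 replicate 1 (0.0607), where 1 member rose and 1 fell, and with its probes averaged (0.0829). Adjusted over the list alone, the counts of these lists were unchanged, and neither was called (adjusted p = 0.605 for mesenchymal and 0.723 for epithelial markers). The epithelial list had a median of -0.019 and a mean of 0.045.

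**Figure D2:**
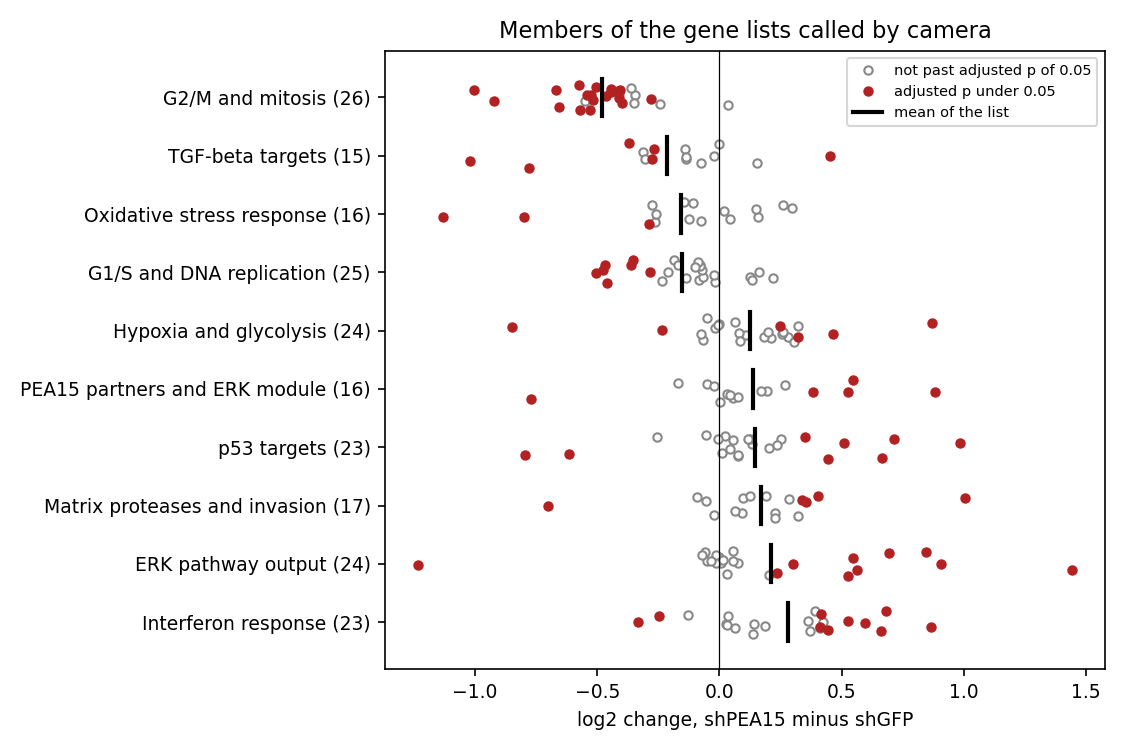
Log2 change of each measured member (horizontal axis, shPEA15 minus shGFP) in the 10 gene lists called by camera (vertical axis, measured members in brackets). Filled points passed a limma adjusted p of 0.05, open points did not, and black bars are list means, from -0.48 for G2/M and mitosis to 0.28 for the interferon response.

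Genes of the p53 response were higher on balance, with exceptions. Of 23 measured p53 targets, 6 rose and 2 fell, and 9 rose and 2 fell when adjusted over the list alone. GADD45A, a DNA damage response gene, rose by 0.99 ± 0.080 (adjusted p = 0.000174), CDKN1A rose as above, and the death receptor gene TNFRSF10B rose by 0.51 ± 0.066 (adjusted p = 0.00168), or by 0.28 with its probes averaged. GDF15, a stress cytokine, changed by -0.80 ± 0.078 (adjusted p = 0.000424). Camera called the list higher (adjusted p = 0.00457, and adjusted p = 0.418 with an estimated correlation), and fry did not (adjusted p = 0.0554). Rises numbered 4 without shGFP replicate 1 or shGFP replicate 2, and 5 without shGFP replicate 3. The number that fell was 1 without shGFP replicate 2, shPEA15 replicate 1 or shPEA15 replicate 2. Of 19 measured death receptor pathway genes, 4 rose and 3 fell, and 6 rose and 3 fell when adjusted over the list alone. BID, which links death receptors to mitochondria, changed by -1.20 ± 0.071 (-0.62 with its 3 probes averaged), and DEDD, another death effector domain gene, by -0.58 ± 0.057 (-0.31 with its probes averaged). TNFRSF10A, the other TRAIL receptor gene with a call, rose by 0.46 ± 0.089. The list was not called (adjusted p = 0.366). The number that rose was 2 without any 1 of the shGFP arrays. Of 19 BCL2 family and apoptosome genes, 3 rose and 0 fell, the same when adjusted over the list alone. PMAIP1 rose as above, and CASP9 rose by 0.28 ± 0.053, a call lost without shGFP replicate 1 (adjusted p = 0.0518) and with its probes averaged (0.0516). BAD rose by 0.30 ± 0.067, a call lost without any 1 of the shGFP arrays or shPEA15 replicate 2 (adjusted p up to 0.0861), and with its probes averaged (0.12). The number that rose was 1 without shGFP replicate 1. The list was not called (adjusted p = 0.0942), except with probes averaged (0.0308), the probe of largest interquartile range (0.0325), fry (0.0156) or without shPEA15 replicate 1 (0.0476).

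The glucose transporter genes SLC2A1 and SLC2A3 changed in opposite directions. SLC2A1, which encodes GLUT1, changed by -0.85 ± 0.072 (adjusted p = 0.000217), and SLC2A3, which encodes GLUT3, rose by 0.87 ± 0.087 (adjusted p = 0.000466). Of 24 measured hypoxia and glycolysis genes, 4 rose and 2 fell, and 10 rose and 2 fell when adjusted over the list alone. Camera called the list higher (adjusted p = 0.00714, and adjusted p = 0.337 with an estimated correlation), but not among brighter probes (0.0606), nor did fry (0.0554). The number that rose was 1 without shGFP replicate 1, and 2 without shGFP replicate 2 or shGFP replicate 3, and only 1 fell without any array except shPEA15 replicate 3. Of 16 oxidative stress response genes, 0 rose and 3 fell, and 1 rose and 5 fell when adjusted over the list alone. AKR1C2, an aldo-keto reductase, changed by -1.13 ± 0.059 (-0.18 with its 6 probes averaged), and TXNRD1, a thioredoxin reductase, by -0.80 ± 0.064. GCLC, of glutathione synthesis, changed by -0.29 ± 0.077, a call lost without any array except shPEA15 replicate 1 (adjusted p up to 0.18). Camera called the list lower (adjusted p = 0.0337, and adjusted p = 0.276 with an estimated correlation). Without shPEA15 replicate 3, 2 rose and 2 fell. The call was lost without shPEA15 replicate 3 (0.125), shGFP replicate 2 (0.0611) or shGFP replicate 3 (0.0546), among brighter probes (0.0701) and on ranks (0.196).

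Lipid genes moved in both directions. Of 16 fatty acid synthesis and storage genes, 1 rose and 4 fell, and 4 rose and 5 fell when adjusted over the list alone. After FADS1, the elongase gene ELOVL6 (-0.96 ± 0.084) and the lipid droplet gene PLIN2 (-0.61 ± 0.11) fell. The list was not called by camera (adjusted p = 0.345) and was called lower by fry (0.00742). The number that rose was 0 without shGFP replicate 1, and 2 without shPEA15 replicate 1 or shPEA15 replicate 3. Of 16 cholesterol synthesis and uptake genes, 2 rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.406). These were DHCR7 (0.49 ± 0.091), lost without shGFP replicate 1 (adjusted p = 0.0677), and HMGCS1 (0.60 ± 0.16), lost without any array except shPEA15 replicate 3 (adjusted p up to 0.18). In all, 3 rose and 1 fell without shPEA15 replicate 3. Of 15 insulin signalling genes, IGFBP1 fell (-1.13 ± 0.13) and PIK3R1 rose (0.39 ± 0.075, or 0.12 and not called with its probes averaged), the latter lost without shGFP replicate 1 (0.0703) or shGFP replicate 3 (0.0516), with the same counts adjusted over the list alone. That list was not called (adjusted p = 0.931), and its mean of -0.035 lay opposite to camera's direction.

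Of 20 autophagy and lysosome genes, 1 rose and 2 fell, and 5 rose and 3 fell when adjusted over the list alone. MAP1LC3B, which encodes the autophagosome protein LC3B, changed by -1.06 ± 0.062 (adjusted p = 3.86e-05) and ATG5 by -0.42 ± 0.071, and the list was not called (adjusted p = 0.727). The rise was ATG12 (0.29 ± 0.063), a call lost without any 1 of the shGFP arrays (adjusted p up to 0.0812) and with its probes averaged (0.0612). In the list, 0 rose without shGFP replicate 1 or shGFP replicate 3, and 2 rose without shPEA15 replicate 3. Of 21 ATF4 and amino acid response genes, 1 rose and 1 fell, and 2 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.579). TRIB3 rose by 0.54 ± 0.071, and the amino acid transporter gene SLC7A5 changed by -0.50 ± 0.10, a call lost without any 1 of the shGFP arrays or shPEA15 replicate 2 (adjusted p up to 0.066). Of these genes, 3 fell without shPEA15 replicate 3. Of 17 endoplasmic reticulum chaperone genes, 0 rose and 2 fell, the same when adjusted over the list alone, with CANX, which encodes calnexin, at -0.65 ± 0.062 (camera adjusted p = 0.579). The other was MANF (-0.33 ± 0.063), lost without shGFP replicate 1 (0.0674) or shGFP replicate 3 (0.0544). In the oxidative phosphorylation list, ATP5MC1 was the only call among 20 genes, also when adjusted over the list alone (camera adjusted p = 0.191), and 1 gene fell without shPEA15 replicate 3. Of 20 cytosolic ribosomal protein genes, RPS3 alone was called, at -0.59 ± 0.070, also when adjusted over the list alone (camera adjusted p = 0.579). Of 12 small RNA machinery genes, 1 rose and 2 fell, and 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.456). Within it, TNRC6A (0.48 ± 0.067, or 0.21 with its probes averaged) rose and TNRC6B (-0.55 ± 0.093) fell, the latter not called with its probes averaged (adjusted p = 0.102). The other fall, DROSHA (-0.47 ± 0.10), was lost without shGFP replicate 1, shGFP replicate 3, shPEA15 replicate 1 or shPEA15 replicate 2 (adjusted p up to 0.118).

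Camera called none of the lists of liver and other cell type markers. Many of their members were too dim to be told from background, so these lists are a weak test of a shift. Only 9 of 25 hepatocyte, 9 of 14 biliary and progenitor, 7 of 12 fibroblast and stellate, 5 of 10 endothelial and 5 of 12 leukocyte genes lay above the median of the table. Of 25 measured hepatocyte genes, 2 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.812). The liver transcription factor genes CEBPA (0.51 ± 0.081) rose and FOXA1 (-0.36 ± 0.056) fell. The other calls were FOXA2 (0.32 ± 0.082), lost without any of the 6 arrays (adjusted p up to 0.13), and AFP (-0.29 ± 0.073), lost without any array except shPEA15 replicate 2 (adjusted p up to 0.136). Of 14 biliary and progenitor markers, 1 rose and 2 fell, and 1 rose and 3 fell when adjusted over the list alone (camera adjusted p = 0.812, median 0.032, mean -0.0044). SPP1, which encodes osteopontin, changed by -0.34 ± 0.063 and SOX4 by -0.35 ± 0.065, calls lost without shGFP replicate 1 (adjusted p = 0.0609 and 0.0548). The rise was CD24 (0.37 ± 0.083), lost without shGFP replicate 1, shGFP replicate 3, shPEA15 replicate 1 or shPEA15 replicate 2 (adjusted p up to 0.121) and with its probes averaged (0.129). Of 12 fibroblast and stellate markers, ACTA2 rose (0.73 ± 0.073) and COL1A1 fell (-0.32 ± 0.067), the latter lost without shGFP replicate 1 (0.087) or shPEA15 replicate 2 (0.0636), with the same counts adjusted over the list alone (camera adjusted p = 0.723). Of 10 endothelial markers, 0 passed, also when adjusted over the list alone, and VWF had the smallest p (-0.057 ± 0.053, limma adjusted p = 0.677). CD68, a lysosomal protein of macrophages, was the only call among 12 leukocyte markers, at 0.38 ± 0.088, also when adjusted over the list alone, and was lost without shGFP replicate 1 (adjusted p = 0.117), shGFP replicate 3 (0.108) or shPEA15 replicate 1 (0.0681). Camera called neither list (adjusted p = 0.575 for endothelial and 0.579 for leukocyte markers). Among 19 genes that lie near PEA15 on its chromosome, 2 rose and 1 fell, the same when adjusted over the list alone (camera adjusted p = 0.312, fry 0.0405). NCSTN, a subunit of gamma-secretase, rose by 0.90 ± 0.056 and PEX19 by 0.46 ± 0.082, and DEDD fell as above. Without shPEA15 replicate 3, 2 rose and 2 fell.

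Camera called 10 of the 33 lists, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05. Of 146 called list members, 84 stayed called whichever array was left out and 62 did not.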

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

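All alternatives were chosen before the data were examined, except counts of list members without each array, which stand beside those lists. No called value reversed under any of them. PEA15 stayed called, at -2.93 to -3.03, and so did the 20 genes with the largest changes in all 336 values of these 21 genes. Those 20 genes were chosen for large changes in these same arrays, so their staying called is weak support. Against 1870 genes (920 rises, 950 falls), an adjusted p under 0.01 left 889 (392 rises, 497 falls), a 1.5-fold change 447 (164 and 283) and treat with a 1.2-fold limit 351 (135 and 216), as stricter rules must. With each array left out in turn, 922 to 2221 genes passed, with 402 to 1076 rises and 520 to 1145 falls. The lowest counts came without shGFP replicate 1 and the highest without shPEA15 replicate 3, the array farthest from its group. Same-numbered arrays did not deviate alike: their deviations correlated at -0.046, -0.42 and -0.27 across genes with means above the table's median. Differently numbered arrays of opposite groups correlated at 0.0044 to 0.39, highest for shGFP replicate 3 with shPEA15 replicate 2. Deviations cancel out within a group, so these values depend on each other. An unlabelled batch or another pairing of the arrays was not tested. With the number as a replicate block, 1084 genes passed (495 rises, 589 falls), 1069 of them also called without it, and no list changed its call. Of the named genes, 18 lost their call with this block and 126 kept their side of the threshold. Averaged probes left 47 genes with at least a 2-fold change instead of 78. Whether dim probes or brighter ones that changed less account for this was not tested. An estimated correlation left 0 of 10 lists called by camera, 5 of them with an unadjusted p under 0.05, and leaving out single arrays gave 8 to 12 lists. The other settings gave 1640 to 2223 genes and 7 to 11 lists, and testing all probes singly gave 2438 probes, unnamed ones included. Repeated quantile normalization and median centring moved nothing, since the table already had equal quantiles, and so say nothing about stability. Of the named genes' alternative values, 1382 kept their side of the threshold, 44 lost the call and 11 gained it, and with arrays left out these numbers were 782, 76 and 6. Of the 1870 calls, 1869 had means above the table's median, where 12189 of the 20044 genes lay. Whether dimmer genes were unchanged or hidden by background cannot be told, since background was not measured.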

Other observations

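The gene families in the next paragraph were picked after their values were seen. Of the tests of patterns further on, those of the G1/S list, of the mitotic list without shPEA15 replicate 3, of changes under 2-fold, and both for shPEA15 replicate 3 were chosen after the result was seen.

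Of 12 measured metallothionein genes, whose products bind zinc and other metals, 5 rose, 0 fell and 7 did not pass in limma. None of the families here was tested as a group. MT1X (0.88 ± 0.14) and MT1F (0.87 ± 0.089) rose most (log2 change ± SE, 3 arrays per group), followed by MT1E (0.54 ± 0.083), MT1G (0.54 ± 0.085) and MT2A (0.38 ± 0.073). Of 4 aldo-keto reductases of the AKR1C group, which reduce steroids, 3 fell: AKR1C3 (-1.66 ± 0.062), AKR1C4 (-1.42 ± 0.10) and AKR1C2 (-1.13 ± 0.059). Their sequences are nearly alike, so probes can read each other's transcripts and the number of genes that changed is uncertain, as it is for metallothioneins. Of 17 alpha and beta tubulin genes with a number in their symbol, 5 rose and 0 fell. The gene TUBB and other tubulin classes were not counted. The rises were all of the beta class: TUBB4A (0.79 ± 0.072), TUBB3 (0.49 ± 0.085), TUBB2A (0.49 ± 0.094), TUBB6 (0.36 ± 0.067) and TUBB2B (0.32 ± 0.084). With an offset of 50 before the log, 4 of these tubulins rose and the other counts were the same.

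The real grouping of the arrays gave 1870 genes in limma, and the highest of the other splits 0 (995 at an unadjusted p under 0.05), so 1 of the 10 splits gave as many. It gave 10 lists in camera, and the highest other split 2, so again 1 of 10 splits gave as many. The 10 splits are too few for a share under 0.05. Every other split also put arrays of both shRNA groups on each side. A difference between the groups then adds to the residual spread, so low counts there are no measure of chance.

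The lower mitotic genes were weighed first. Their median change of -0.45 lay below all of 10000 random lists matched on mean value (central 95% from -0.095 to 0.14), which argues against a shift of all genes of that brightness. Without shPEA15 replicate 3 the mean change was -0.45, against -0.48 with it, so that array alone does not account for it. Fewer cycling cells may be the reason: the G1/S list was lower too (-0.15), but not by as much, as had been set out for this reason. The G2/M list lay a further -0.33 from it (SD 0.069 over shPEA15 arrays). Nor did the G1/S list stay level, the result set out against this reason. No value here decides, since no cell count or cycle phase was measured. An effect of PEA15 depletion and an off-target effect of the shRNA stay open and untested, as the shRNA sequence was not used here. The sample titles do not say whether more than 1 shRNA against PEA15 was used.

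Large changes were mostly falls, 76.9% of those of at least 2-fold (exact 95% interval 66.0 to 85.7). Without shPEA15 replicate 3 the share was 72% (54 falls and 21 rises, exact 95% interval 60.4 to 81.8), which argues against that array as the reason. Among called changes under 2-fold it was 49.7% (890 falls and 902 rises, exact 95% interval 47.3 to 52.0). That balance decides nothing about a shifted centre, which stays open, because quantile normalization had already fixed the centre of every array. Genes are not independent, so these intervals are too narrow. Off-target silencing by the shRNA, which lowers transcripts, was not tested and stays open beside an effect of PEA15 depletion.

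The array of shPEA15 replicate 3 stood apart from the other shPEA15 arrays. Over genes with means above the table's median, the SD of its deviations was 0.236, against 0.109 to 0.170 for the other 5 arrays. Its change from control had a slope of 0.98 (SE 0.011, 2221 genes called without it) on that of the other shPEA15 arrays. The slope decides nothing about stronger depletion, since the genes were chosen in the arrays set against it, which lowers the slope. In the same way shPEA15 replicates 1 and 2 gave only 0.848 and 0.897, with shPEA15 replicate 3 among the arrays set against them. A slope under a set limit and a PEA15 value not the lowest had been set out against stronger depletion, and both were seen. PEA15 in shPEA15 replicate 3 was the highest of the 3 (9.74, against 9.63 and 9.71), so PEA15 itself gave no sign of stronger depletion. The values differed by little, so stronger depletion was not excluded. The 76 mitochondrial ribosomal protein genes deviated by a median of 0.071 in that array, inside the range of matched random lists (0.007 to 0.147), so this class was not read lower there. No other reason was tested, and the labels give no batch.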
